A study of Drosophila melanogaster with 2 samples.

How the data were processed

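Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on Drosophila melanogaster embryos collected 8 to 16 h after egg laying, with an antibody against Huckebein, the protein product of the gene hkb. Per the labels' protocols, the embryos were cross-linked with formaldehyde, the chromatin was sonicated, and an aliquot of the same extract served as the input reference. The labels give 1 ChIP sample, whose title names replicates 1 and 2 together, and 1 input sample. A peak list for the ChIP sample was analysed here, and no values of the input sample were analysed.

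The deposited file is a list of intervals with a score per peak, and the authors made it with MACS, per the file headers. Bowtie and the genome build BDGP5 are named in the submitters' processing notes, with no Bowtie version. The MACS version, its threshold, the treatment of duplicate and repeat-mapped reads and the way in which the input was used are not given in the sources used here. MACS by its convention writes a multiple of the negative log10 of the peak p-value in this column, but the file does not state this. The values are therefore called peak scores, and they were used only to describe, rank, filter and compare peaks within the list. How the replicates named in the sample title were combined (pooled reads, merged peaks or shared peaks) is not given in the sources used here either. As 1 list was analysed, there was no replicate spread. Every p-value below compares this list with a random arrangement of its own peaks or compares subsets of its peaks, and none of them tests a condition or a treatment. Read numbers are not given in the file, so the sequencing depth behind each peak is unknown, and no interval for a peak score could be computed.

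Start positions were taken as 0-based, following the BED convention, and are printed 1-based. Peak width was the end minus the 0-based start. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. The arms 2L, 2R, 3L, 3R and X entered the comparisons between arms. Peaks on heterochromatic (Het), unlocalised (U) and unassembled (Uextra) sequence were described separately. Arm lengths of the build were not used here, so the length of an arm was taken as the distance from the first to the last peak on it. The number of peaks on each arm was compared with its share of the summed length by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 5 arms and Clopper-Pearson 95% intervals. As an alternative chosen after the data were seen, peaks were counted in complete 1 Mb bins and the bins were permuted between arms (100000 permutations), which keeps the clustering of peaks within a bin. The ratio of X to autosomal bin means was given a bootstrap interval over bins (2000 draws). The permutation and the bootstrap treat neighbouring bins as independent. Medians of peak score and width were compared by two-sided permutation tests of the difference of medians (100000 permutations), adjusted over the 4 comparisons made, with bootstrap 95% intervals from 2000 draws. These tests and intervals treat peaks as independent. Distances between peak midpoints were compared with 1000 random placements of the same peaks on the same arm, so that the smallest p-value possible was 0.000999. Each placement drew new positions uniformly, and the test is called permutation of peak positions below. The plan left assembly gaps out of the placements, but this was not done here. Sequence to which reads cannot be mapped was not left out either. Placements over the whole arm had no overlap, whereas those within bins or windows allowed it unless a minimum gap was set. Intervals of medians were exact order-statistic intervals. They cover the sampling of peaks only.

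The neighbour test and the binomial test of X were checked on simulated lists of 1589 peaks. The permutation of bins and the placements within bins or with a minimum gap were not checked on simulated lists. With uniform placement, the neighbour test, run here with 200 placements, called 5 of 100 lists at a threshold of 0.05. It called 100 of 100 lists in which 1 in 5 peaks had been moved to within 5 kb of another. The moved peaks and their new neighbours made up more than the 28.9% observed in the deposited list. Detection of an excess of the observed size was thus not checked. The binomial test of X called 7 of 100 lists with X not changed and 100 of 100 with X raised 1.3-fold; those simulated peaks were independent of each other.

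The peaks named in the text were fixed before the data were examined as the 12 with the highest scores and the 5 widest, to be used where no annotation of the files' build was at hand; other regions named below were chosen after their values were seen. The planned tests of promoters, feature classes, DNA words and 19 gene lists needed the sequence and annotation of BDGP5 and were not run. The gene table at hand describes Release 6 of the genome, so it was used only for the identity of hkb, and no gene was assigned to a peak. Alternatives were the peaks scoring above the median (106.58), the main arms alone, and merging of peaks less than 1000 bp apart, with others added after the data were seen.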

Results

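The data comprised 1 list of Huckebein-bound regions from embryos aged 8 to 16 h. Huckebein is a zinc-finger transcription factor encoded by hkb (NCBI Gene 40549, Dmel_CG9768), a protein-coding gene on 3R. It is known as a terminal gap gene product of the early embryo that acts in the endoderm, and it is later used in the salivary gland and in neuroblasts. The series asked where this factor binds in the genome, relative to input chromatin, in embryos of this age. All positions below are 1-based on BDGP5.

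Huckebein ChIP-seq yielded 1623 peaks, of which 1589 (97.9%) lay on the 5 large chromosome arms. These 1589 peaks covered 0.976% of the 115 Mb between the first and last peaks of the arms. Arm 3R carried 373 peaks, X 377, 2R 325, 3L 280 and 2L 234. Chromosome 4 had 0 peaks in the list, which holds only regions that passed the authors' peak calling. A further 31 peaks lay on U and Uextra and 3 on Het sequence. The median peak width was 642 bp (95% interval 625 to 658) and the range was 117 to 2409 bp. The authors' peak scores ran from 50 to 2102.67, with a median of 106.58 (95% interval 101.27 to 112.92). Scores under 60 were held by 209 peaks (12.9%), whereas 69 peaks (4.25%) scored 500 or more.

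The highest-scoring region lay on 3R at 909979 to 911774, with a score of 2102.67 over 1796 bp. The next 3 were on X. The X peak at 8294942 to 8296613 scored 1759.86, the one at 7945653 to 7946647 scored 1628.56 and the one at 10500468 to 10502412 scored 1286.7. Each of these 3 X peaks had another peak close by, with midpoints 1.40, 2.53 and 2.63 kb away, respectively. The highest 3R peak was isolated, its nearest neighbour being 63.7 kb away. X held 5 of the 12 highest-scoring peaks, the others on this arm being 1541490 to 1543076 (score 1250.84) and 14897970 to 14899323 (score 1006.79). The nearest neighbours of these were farther off, at 10.8 and 55.8 kb, respectively. Arm 3R held 4 of the 12, including 25382435 to 25383609 (1261.96), 14020660 to 14022291 (1058.02) and 15470802 to 15471855 (987.21). Arm 3L held 17069775 to 17070891 (1103.6) and 13884296 to 13885172 (968.8), and 2L held 13475227 to 13476387 (996.66). Arm 2R had none of the 12, and its highest peak score was 833.97. With a single list these scores have no replicate error, so the order of peaks with similar scores was not tested.

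The widest regions were mostly not the highest-scoring ones. The widest peak, on 3R at 16151453 to 16153861, spanned 2409 bp and ranked 792 of 1623 by score, at 109.89. The next 4 were 3L 8458924 to 8461201, 2L 8826510 to 8828753, 3R 24923691 to 24925879 and 2L 6093000 to 6095135, with widths of 2278, 2244, 2189 and 2136 bp and score ranks of 120, 211, 244 and 346. Across the 1589 arm peaks, width and score were correlated (Spearman's rho = 0.60, Pearson's r of the logarithms = 0.61, permutation p = 1e-05, the smallest that 100000 permutations can give). This correlation is across peaks of 1 list, and peaks are not independent replicates.

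The X chromosome carried the highest density of Huckebein peaks. It had 17.6 peaks per Mb, against 12.9 per Mb on the autosomal arms together, a ratio of 1.36 (95% interval 1.21 to 1.53). Relative to a distribution by length, X had 1.28 times the expected number (95% interval 1.16 to 1.39, adjusted p = 1.66e-06, exact binomial test). Arm 2L had the lowest density, 10.5 peaks per Mb and 0.77 times the expected number (95% interval 0.68 to 0.86, adjusted p = 7.01e-06, exact binomial test). Arm 2R was above expectation at 1.14 times and 3L below it at 0.88 times (adjusted p = 0.0154 for each, exact binomial test), and 3R was at 0.97 times (adjusted p = 0.597). Peaks within an arm were not evenly spread. The variance of the number of peaks per 1 Mb bin was 3.81 times the mean, so the binomial p-values are too small and the binomial intervals of the arms and of the density ratio are too narrow. When whole bins were permuted between arms, X still differed from the other arms, with 18.1 ± 9.04 peaks per bin (SD over 20 bins) against 12.8 ± 6.44 (SD over 88 bins) and an adjusted permutation p of 0.0151. The ratio of these means was 1.41, with a bootstrap interval over bins of 1.09 to 1.79. The call did not hold without the densest bin of X, 19000001 to 20000000, where the adjusted permutation p was 0.0619 and the ratio 1.32. This bin was picked for its count and no autosomal bin was removed, so the removal could only weaken the difference. Dense bins also lay side by side, as in X 18000001 to 19000000 with 31 peaks and the next bin with 39. Neither the bin permutation nor the bootstrap keeps such runs of bins. The permutation p-values may therefore be too small and the bootstrap intervals over bins too narrow. The same permutation test gave adjusted p = 0.0547 for 2L, 0.507 for 2R and 0.491 for 3L, so the differences of these 3 arms did not pass the threshold of 0.05 over bins.

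**Figure D1:**
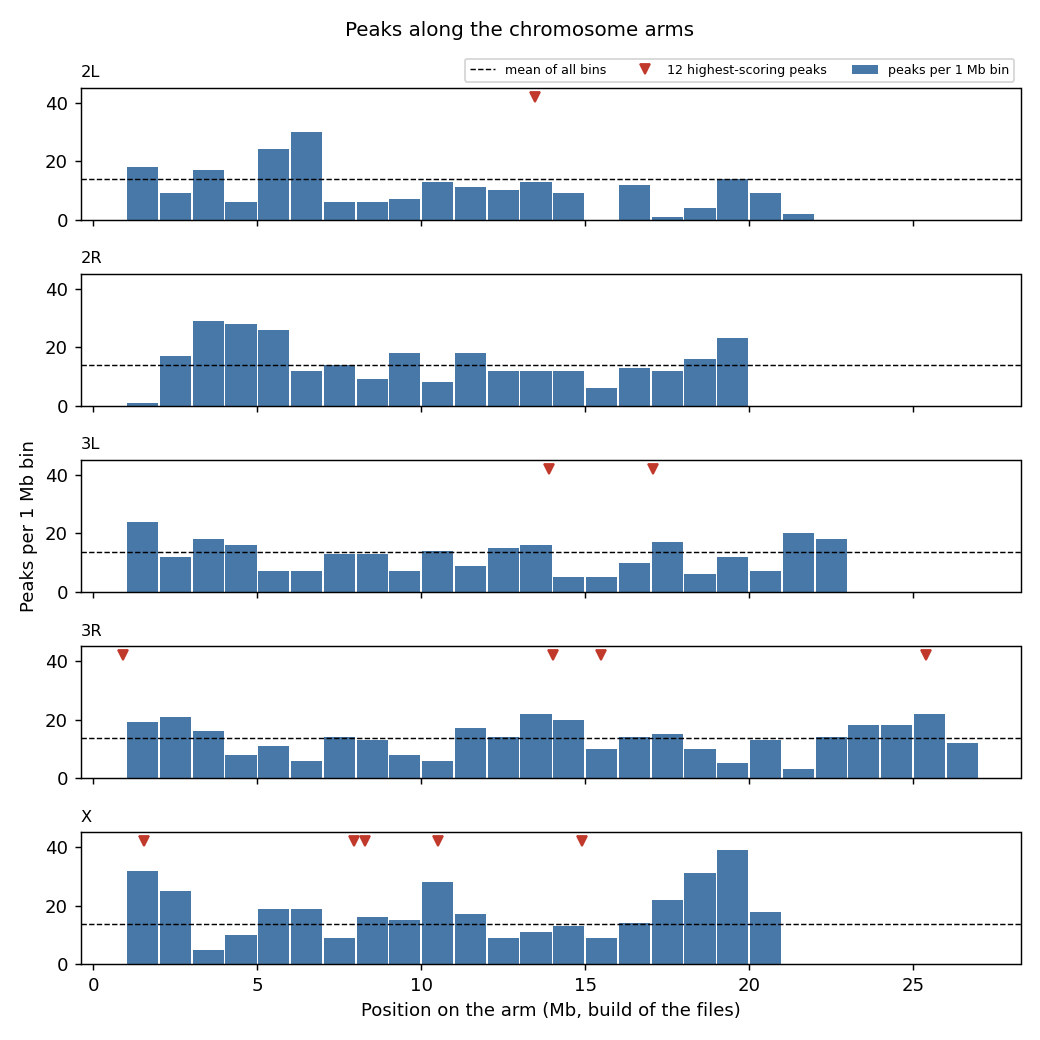
Peaks per complete 1 Mb bin (vertical axis) along each of the 5 arms (horizontal axis, position in Mb), with the mean of all bins as a dashed line and the 12 highest-scoring peaks as triangles placed at an arbitrary height. The tallest bar is the X bin of 39 peaks, and 2L has a bin with 0 peaks; incomplete bins at the ends of the peak-covered length are not drawn.

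Among X peaks, 27.9% scored 200 or more, against 21.04% of autosomal peaks (105 and 255 peaks, adjusted p = 0.022, Fisher's exact test over 3 score classes). The shares scoring 100 or more (55.4% and 51.9%, adjusted p = 0.357, Fisher's exact test) and 500 or more (4.77% and 3.96%, adjusted p = 0.464, Fisher's exact test) did not pass. An X peak outscored an autosomal peak in 53.7% of all pairs (two-sided permutation p of the ranks = 0.0305). The medians were not distinguishable. The median score was 114.55 on X and 104.66 on the autosomal arms, a difference of 9.90 (95% bootstrap interval -4.45 to 25.5, adjusted p = 0.199, permutation test). X peaks were narrower, with a median of 614 bp against 658 bp (difference -44 bp, 95% bootstrap interval -74.0 to -5, adjusted p = 0.0342, permutation test). The ratio of X to autosomal density over 1 Mb bins was 1.51 (95% bootstrap interval over bins 1.20 to 1.89) for peaks scoring 100 or more. For peaks scoring 200 or more it was 1.90 (1.36 to 2.60). For the peaks scoring 500 or more, 18 on X and 48 on the autosomal arms, it was 1.80 (0.931 to 3.14). That interval includes equal density, whereas permutation of the bins gave an unadjusted two-sided p of 0.0478, so this class was not settled. Complete bins leave out peaks near the ends of the arms. By length, with those peaks kept, the ratios of the 3 classes were lower, at 1.46, 1.80 and 1.64. The score classes and the tests on them were chosen after the data were seen. The Fisher and rank tests treat peaks as independent, as do the tests and intervals of the medians. The width difference, close to the threshold, was not tested over bins.

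Huckebein peaks lay closer together than peaks placed at random along the arms, with assembly gaps and unmappable sequence not left out of the placements. A neighbour within 5 kb was found for 460 of the 1589 arm peaks (28.9%), against 11.5 ± 1.06% (mean and SD of 1000 random placements), a ratio of 2.51 (p = 0.000999, the smallest that 1000 placements can give, one-sided permutation of peak positions). The median distance between neighbouring midpoints was 34.4 kb as deposited and 49.5 kb in random placements (p = 0.000999, permutation of peak positions). The excess was present on each arm. X had 35.5% of its peaks within 5 kb of another (random mean 14.1%), 2R had 34.2% (12.5%), 3L 29.6% (9.82%), 2L 24.4% (8.74%) and 3R 20.1% (10.9%), each with an adjusted p of 0.000999. Placement of the peaks at random within their own 1 Mb bins gave 15.2% (central 95% of placements 12.8 to 17.6%), also below the observed share, and placement within their own 100 kb windows gave 19.0% (16.5 to 21.3%). The share depended on how close peaks were joined: it was 18.6% after merging peaks less than 1000 bp apart and 11.5% after merging those less than 2000 bp apart, against 8.31% and 5.42% in placements with the same minimum gap (p = 0.000999 for each, permutation of peak positions). Against placements with no minimum gap, the latter share was 1.16 times the random mean (p = 0.0729, permutation of peak positions).

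**Figure D2:**
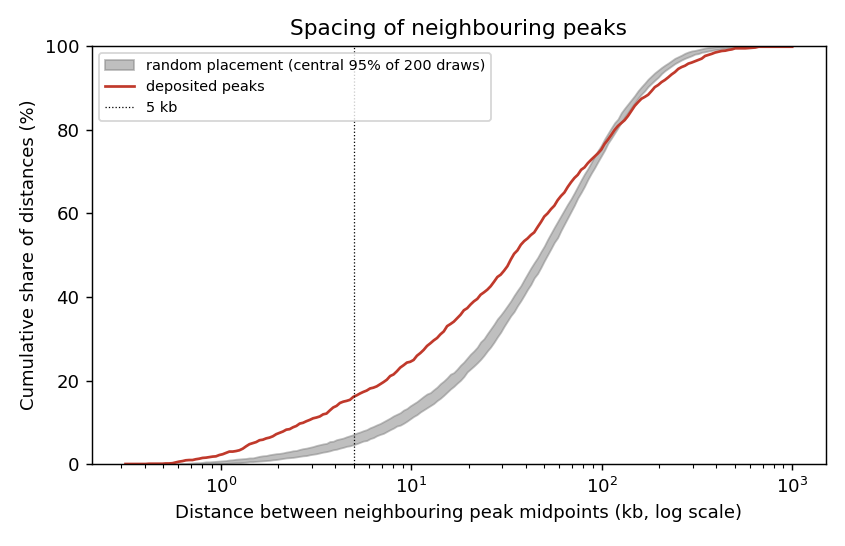
Cumulative share of distances between neighbouring peak midpoints (vertical axis, %) against distance (horizontal axis, kb, log scale) for the deposited peaks (line) and for 200 random placements (band, central 95%). The line lies above the band at 5 kb and at the shorter distances, and its median distance is 34.4 kb.

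The densest stretch was on X, where 13 peaks lay between 1284629 and 1372336 (87.7 kb, highest score 320.9). Random placements reached 7.71 ± 0.801 peaks in their densest 100 kb (mean and SD, p = 0.000999, one-sided permutation of peak positions). Placements within the same bins reached 9.56 ± 1.07 (p = 0.014, permutation of peak positions). A second stretch of X, 19535895 to 19636860, held 12 peaks, and X 18689011 to 18785719 held 10. On 2R, 10 peaks lay between 3096404 and 3186802, and on 3R, 9 peaks lay within 38.0 kb, from 3100898 to 3138936. The longest stretches without a peak were 2R 763254 to 1980189 (1217 kb), 2L 14909144 to 16046834 (1138 kb) and 2L 16869705 to 17972402 (1103 kb). The longest distance in random placements averaged 615 kb, and the observed longest distance between midpoints was 1218 kb, 1.98 times as long (p = 0.000999, permutation of peak positions). In placements within the same 1 Mb bins it averaged 1196 kb (p = 0.356, permutation of peak positions). The observed longest distance thus did not exceed what the number of peaks per bin gives. The stretches named here were chosen after their values were seen.

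**Figure D3:**
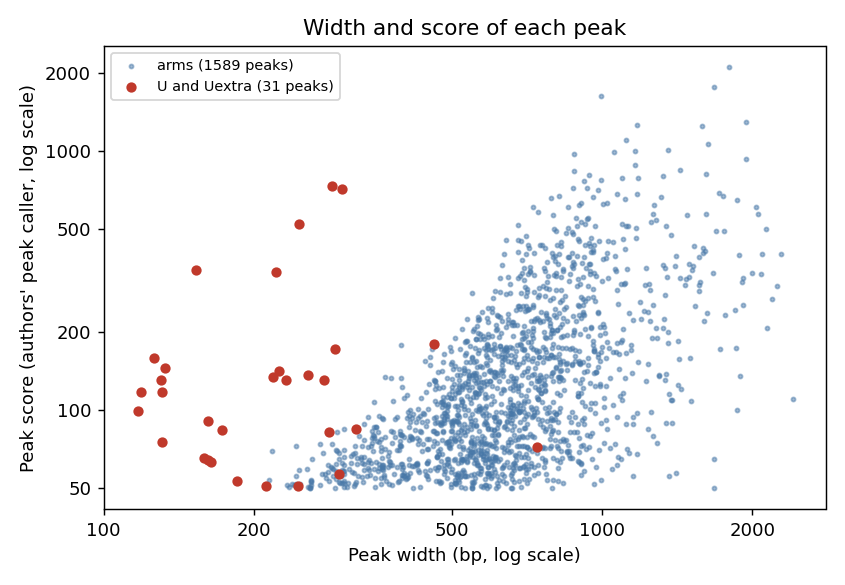
Peak score (vertical axis, log scale, as given by the authors' peak caller) against peak width (horizontal axis, bp, log scale), 1 point per peak, for 1589 arm peaks and 31 peaks on U and Uextra. The U and Uextra points sit to the left, with a median width of 219 bp against 648 bp on the arms.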

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

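The tests of the unplaced peaks against arm peaks of equal score, of the X density among peaks scoring above the median, of broad sites with a matching minimum gap, of 100 kb windows and of merged peaks within bins, and the bootstrap over bins, were chosen after results had been seen. What the tests of merged X clusters, of median bins and of 1 Mb regional density would show was written before their results but after the peak list, and the X density, had been seen. No biological explanation was tested: the labels give no second ChIP group to compare, and the tests against promoters, DNA words and gene lists were not run without sequence and annotation of the build.

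A total of 34 peaks lay outside the 5 arms, in sequence that the arm comparisons do not use. These were 24 peaks on Uextra, 7 on U and 3 on Het sequence, and they are given here because a signal appeared in data outside the main measurement. The 31 on U and Uextra had a median width of 219 bp against 648 bp on the arms (difference -429 bp, 95% bootstrap interval -493 to -395, adjusted p = 4e-05, permutation test). Their median score was 117.77 against 106.53 (difference 11.2, 95% bootstrap interval -25.3 to 32.1, adjusted p = 0.581, permutation test). Arm peaks of the same score decile were 2.81 times as wide (95% bootstrap interval 2.40 to 4.15), but as the median score on U and Uextra was not below that of the arms, matching on score had little to remove and decides nothing about the narrowness. The 3 highest, Uextra 18119426 to 18119712, 22164620 to 22164919 and 3204688 to 3204933, scored 733.25, 710.62 and 523.71 over 287, 300 and 246 bp. Reads from repeated sequence piling up on short contigs, or contig ends that cut peaks short, may each give such narrow, high peaks; neither was tested, as contig bounds and repeats were not used here.

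Among the U peaks, 6 lay within 12.1 kb in the coordinates of U, from 5288464 to 5300513, with scores of 90.82 to 346.88 and widths of 133 to 291 bp. As contig bounds were not used, whether they lie on the same contig is unknown. The 2RHet peak, with a score of 252.28, began 30 bp before the first base of its sequence.

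The higher peak density on X was weighed against 3 technical explanations. Peaks near the score threshold do not account for it, because the X to autosome ratio among peaks scoring above the median was 1.55 over 1 Mb bins (95% bootstrap interval over bins 1.21 to 1.97). By length, with the peaks outside complete bins kept, this ratio was 1.47. Repeated counting of close clusters stays open in part: with peaks less than 5000 bp apart merged, the ratio over bins was 1.29 (95% bootstrap interval 1.04 to 1.58), and the lower bound fell short of the 1.1 set beforehand. By length, the ratio after this merging was 1.23. A few dense regions of X also stay open, as the ratio of median peaks per 1 Mb bin was 1.32 with a bootstrap interval of 0.926 to 1.71. Read depth and copy number of X relative to the autosomes, in ChIP and in input, could shift the calling of peaks and were not tested, since the list gives no reads.

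The closeness of neighbouring peaks was weighed against 2 technical explanations. Broad sites listed as several peaks do not account for all of it: after merging peaks less than 2000 bp apart, 11.5% (11.54) of peaks had a neighbour within 5000 bp, against a central 95% of 3.85 to 6.99% in placements that kept the same minimum gap. A first version of that test allowed random peaks any gap, which merged peaks cannot have, and gave 7.97 to 12.1%, an interval that includes the observed share. Density at the scale of 1 Mb does not account for all of it either, since placement within the same 1 Mb bins gave 15.2% against 28.9% observed. It may account for part, as placement over the whole arm gave a lower share of 11.5%. Within 100 kb windows placement gave 19.0%. Merged peaks placed within 1 Mb bins gave 6.35% (4.83 to 8.04%), against 11.5% observed after merging. Broad sites together with density below 1 Mb were not tested and stay open. Assembly gaps and unmappable sequence, which the placements did not leave out, were not tested either. Pairs of elements in the same regulatory regions may be a biological source, also not tested.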

How the results depend on the processing

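Of 42 alternative values, 31 kept their side of the threshold or stayed within their limits, 7 fell short of the threshold and 4 moved. Of the results that passed the threshold as deposited, 0 reversed. The ratio for 3R did not pass as deposited (0.97), and it crossed to 1.01 after merging at 1000 bp (adjusted p = 0.88, exact binomial test). Above the median score there were 811 peaks, by construction, with a median width of 763 bp and a median score of 184.73; merging peaks less than 1000 bp apart gave 1520 peaks with a median width of 659 bp. The ratio of observed to expected peaks no longer passed the exact binomial test above the median score for 2R (1.15, adjusted p = 0.0962) and 3L (0.88, adjusted p = 0.115), each with fewer peaks tested. Permutation of 1 Mb bins, which compares an arm with the other arms, gave 0.72 for 2L (adjusted p = 0.0547), 1.11 for 2R (0.507) and 0.87 for 3L (0.491), and without the densest bin of X it gave 1.32 for X (0.0619). X remained above expectation and past the threshold in the other 3 alternatives, at 1.24 to 1.41. The share of peaks with a neighbour within 5000 bp was 18.3% above the median score, 18.6% after merging at 1000 bp and 11.5% after merging at 2000 bp. Each had p = 0.000999 against random placements, which kept a matching minimum gap for the merged settings (permutation of peak positions). Against placements with no minimum gap, the share after merging at 2000 bp had p = 0.0729 (permutation of peak positions). Bin permutation and bootstrap, placement within bins, the density ratios, and merging for the neighbour share and distance (1000 and 2000 bp) and for the density ratio (1000 and 5000 bp) were chosen after the data were seen. Settings that use transcription start sites or sequence were not run. No paired analysis was possible because the ChIP sample has 1 list, with no values per replicate, and no input values were analysed. Sequencing depth is unknown, so weakly bound regions under the authors' threshold could not be told from unbound ones.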

Other observations

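Peaks that lie close to another peak were asked whether they score higher, a hypothesis written down before the test. The median score was 112.2 for the 460 arm peaks with a neighbour within 5000 bp and 103.97 for the other 1129. The difference of 8.23 (95% bootstrap interval -4.13 to 21.7, two-sided permutation p = 0.201) did not exceed the spread between peaks, so the hypothesis was not borne out in this list.

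Within arms, the densest complete 1 Mb bins were X 19000001 to 20000000 with 39 peaks, X 1000001 to 2000000 with 32 and X 18000001 to 19000000 with 31, followed by 2L 6000001 to 7000000 with 30 and 2R 3000001 to 4000000 with 29. The sparsest were on 2L, with 0 peaks from 15000001 to 16000000 and 1 peak from 17000001 to 18000000, and on 2R, with 1 peak from 1000001 to 2000000.

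The 31 peaks on U and Uextra showed no detectable correlation of width with score (Spearman's rho = 0.13, Pearson's r of the logarithms = 0.13, permutation p = 0.483), against a rho of 0.60 for the arm peaks; the difference between these correlations was not tested.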
